A study of Canis lupus familiaris with 81 samples.

How the data were processed

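The series profiled canine appendicular osteosarcoma, a bone tumour of the limbs of dogs, with the GeoMx Digital Spatial Profiler. In this assay, probes carrying a DNA tag are hybridised to tissue sections, the tags are released from a chosen region of the section, and the tags are sequenced. Tissue came from dogs enrolled in a clinical trial and was placed on tissue microarrays, which hold small pieces of many specimens on 1 slide. The labels name 2 arrays, here array 1 and array 2. Of 81 libraries, 68 were tumour regions from 24 tumour numbers, 12 were regions of the control tissues kidney, spleen and liver with 4 regions each, and 1 was a no-template control. Each tumour number was taken as 1 tumour, and each had at least 1 region on each array. In 10 tumours there were 2 regions on each array, and in 14 tumours there was 1. The labels do not say which animals the control regions came from or how regions were chosen within a piece of tissue.

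Per the file headers, the deposited values are counts per probe that were written by version 2.3.4 of the GeoMx NGS pipeline. The headers also list the reads left after trimming, stitching and alignment. The summed counts lie far below the aligned reads, as they do where repeated reads of 1 molecule are counted once. The raw and aligned read numbers were used only to describe depth. No normalization of the deposited counts is recorded in the headers. The files give 2010 probe identifiers and do not pair them with gene names. None of the identifiers matched a row of the gene table given for the dog assembly UU_Cfam_GSD_1.0, so probes are reported by identifier. For the same reason the lists of marker genes fixed before the data were examined were not tested, and neither was the estimated correlation planned for them. Negative control probes were not used here, so the non-specific background of each region was not subtracted.

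Total counts in the tumour regions ranged from 17711 to 1069118 with a median of 211967, and those in the control regions from 92126 to 396058. The median count per probe in a tumour region ranged from 2 to 102. Sequencing saturation, computed as the percent of aligned reads in excess of the summed count, was between 95.7% and 98.9% in the tumour regions. Counts of different regions of 1 specimen were compared by a chi-square test over probes with a summed count of at least 10. All 92 pairs differed by more than counting noise, the highest p being 0.000457, so no library is a copy of another of the same specimen. Regions of different specimens were not compared in this way. Separate preparations of the same piece of tissue can differ by more than counting noise too, so this does not tell whether regions on the 2 arrays are repeats. The same chi-square per degree of freedom was used to compare matched regions across arrays with regions of the same array, on probes not used to match them.

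Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter on low counts, Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The filter kept all 2010 probes in the tissue and tumour comparisons and 2008 in the array comparison. For osteosarcoma against each control tissue, the regions of each tumour were summed to 1 sample and the 4 regions of each tissue to 1 sample. The spread therefore came from the 24 tumours, each lone tissue sample was assumed to vary as much as the tumours do, and the tests do not include the variation of a tissue between dogs. For array 2 against array 1, regions were summed per tumour and array, and the tumour was a block because the labels give the same tumour numbers on both arrays. For differences among tumours, the 68 regions entered singly, with array as a covariate and an F test over all tumours. This test asks whether tumours differ by more than the regions within a tumour do.

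The share of variance between tumours was estimated per probe by 1-way variance components on log2 counts scaled to a common library size (CPM, TMM-scaled, prior count 2) centred within each array, with negative estimates set to 0. For region matching, each region was assigned the region of the other array with the highest Pearson correlation over centred probes, and tumour numbers were reassigned within arrays 100000 times for a one-sided permutation p. Total counts on the 2 arrays were compared by a two-sided sign-flip permutation test with 100000 resamples. A tissue-high probe set was chosen from the control regions alone, as the probes above every region of the other tissues in each of the 4 regions of a tissue and at least 1 log2 unit above each of the other means. The level of a set is the mean log2 CPM of its probes per region, then per tumour. Pearson and Spearman correlations were computed over 24 tumours between 5 measures, which makes 10 relations, with permutation p and Benjamini-Hochberg adjustment.

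For each tissue and array comparison, the 2 probes with the largest log2 fold change in each direction among those past the threshold are named. The standard error (SE) printed with a log2 fold change is the absolute fold change divided by the square root of the F statistic. It is not a fitted standard error and does not measure the spread over tumours. It was 0.26 for RTS0111950 and 2.73 for RTS0112269, whose SDs over tumours were 0.37 and 1.40 log2 CPM. For differences among tumours, the 2 past the threshold with the largest share of variance between tumours and a mean level above the median are named. The scripts were tested on simulated data. In the simulated tissue and array comparisons, changed probes were raised or lowered at random and counted together. Their percents therefore do not give the power for each direction. With 24 samples against 1, the tissue test recovered 18.5% of probes changed 2-fold, 73.0% of those changed 4-fold and 94.4% of those changed 16-fold, and it called 0.442% of unchanged probes. The array test recovered 15.6% of probes changed 1.1-fold, 78.8% of those changed 1.25-fold and 100% of those changed 1.5-fold. The test among tumours recovered 67.1% of probes whose tumour effect had an SD of 1.25-fold and 98.6% of those with 1.5-fold.

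The tests, the named-probe rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors, upper quartile scaling or library size alone in place of TMM, no filter on low counts, DESeq2 1.42.0, limma 3.58.1 with voom on regions and the specimen as a random block, regions as samples, single arrays, subsets of tumours, thinned counts and leaving out each control region. Leaving out each tumour, the 10 probes of highest count or the 17 tumour regions with the lowest totals, thinning the arrays to equal totals, other scalings for the order of set levels and their correlations, and using 1 array for differences among tumours were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps. The study grouped dogs by disease-free interval, the time after treatment without return of disease. The labels of the regions do not give the interval group, so that comparison is not analysed here.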

Results

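Counts of 2010 probes were obtained from 68 regions of 24 canine osteosarcomas and from 4 regions each of kidney, spleen and liver on 2 tissue microarrays. Median total counts were 211967 in the tumour regions, 191424 in kidney, 197740 in spleen and 155685 in liver. A few probes took a much larger part of the counts in some tumours than in others. The 10 highest probes of a region held 40.5% ± 18.5 of its counts (SD, n = 24 tumours), from 19.2% in tumour 706 to 72.6% in tumour 610. They held 12.5% to 12.8% in kidney, 11.4% to 12.5% in spleen and 29.1% to 35.7% in liver regions, and 11 of the 24 tumours lay above the highest control region. The share was nearly the same on both arrays, with Pearson r = 0.99 and Spearman rho = 0.963 over 24 tumours. The permutation p was 1e-05 for each, the smallest the permutations can give, and r was 0.993 without the 2 tumours farthest from the median.

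**Figure D1:**
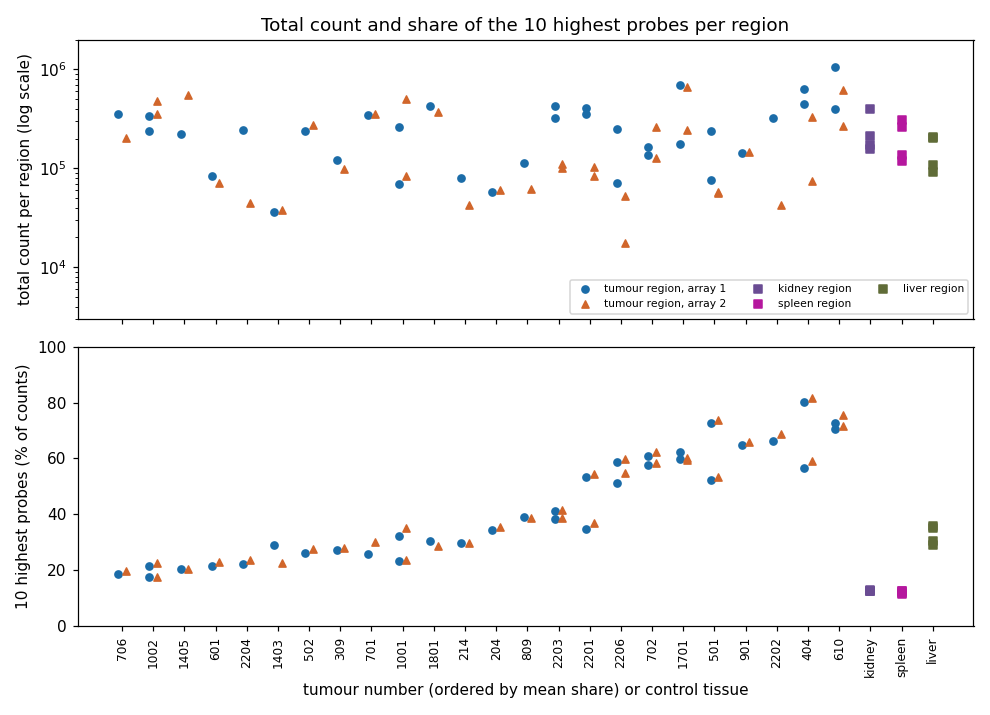
Total count per region on a log axis (top) and percent of counts in the 10 highest probes (bottom) for each tumour, ordered by its mean share, and for the 3 control tissues. Each point is 1 region, circles are array 1, triangles array 2 and squares control tissue. The mean share of a tumour runs from 19.2% in tumour 706 to 72.6% in tumour 610, and that of a tumour region from 17.4% in tumour 1002 to 81.7% in tumour 404.

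Probe RTS0112268 had the highest count in 60 of the 68 tumour regions. It is named here because of its counts and was chosen after its values were seen. It held a median of 18.8% of the counts of a tumour region, with a range of 1.73% to 49.975%, against medians of 0.062% in kidney, 0.079% in spleen and 0.046% in liver, with 4 regions each. Every tumour region was above every control region for this probe. Its edgeR log2 fold change of tumours over liver was 10.08 with a standard error of 3.33, with an adjusted p = 0.0778, so the probe was not among those called.

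Osteosarcoma was compared with each control tissue to find the probes that set the tumours apart. Against kidney, 99 probes were lower and 4 were higher in the 24 tumours. Against spleen, 48 probes were lower and 0 were higher, and against liver 89 were lower and 12 were higher, each of 2010 probes tested. The 503 probes of lowest mean level in the tumours were at 6.281 log2 CPM there, below their level of 6.807 in kidney, 6.721 in spleen and 7.084 in liver. The choice of these probes on the tumours favours that order. With TMM, the 503 lowest in the control tissues were at 6.574 in the tumours, 6.568 in kidney, 6.639 in spleen and 6.843 in liver. With upper quartile scaling these levels were 6.53, 6.871, 6.935 and 7.401, and with library size alone 6.553, 7.365, 7.648 and 7.692. The order of tumours and tissues therefore depended on the scaling. RTS0111950 was at 13020 CPM in kidney and at a median of 73.1 CPM in the tumours, and RTS0111944 was at 23090 CPM in liver and at a median of 135.9 CPM in the tumours. In the comparisons below, the SE of a log2 fold change is the value computed from the F statistic.

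Relative to kidney, RTS0111950 was lower by a log2 fold change of -7.50 ± 0.26 (SE, edgeR adjusted p = 1.95e-20, lower in 24 of 24 tumours) and RTS0112972 by -6.62 ± 0.24 (adjusted p = 7.1e-20, lower in 24 of 24 tumours). RTS0112902 was higher by 4.307 ± 1.252 (adjusted p = 0.0346) and RTS0113204 by 3.51 ± 1.02 (adjusted p = 0.0342), each in 24 of 24 tumours. Under scaling by library size alone, adjusted p for these 2 rose to 0.0708 and 0.18, and on array 1 alone it was 0.0532 for RTS0112902. Relative to spleen, RTS0113819 was lower by -5.62 ± 0.42 (adjusted p = 2.57e-11) and RTS0112353 by -3.92 ± 0.23 (adjusted p = 9.36e-14), both in 24 of 24 tumours. RTS0111950, RTS0112972 and RTS0113819 had mean levels of 6.193, 6.21 and 6.064 log2 CPM in the tumours. These lie near the mean of 6.281 of the 503 probes lowest in the tumours. Background was not subtracted, so the size of these fold changes may depend on it.

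Relative to liver, RTS0111944 was lower by -7.36 ± 0.28 (edgeR adjusted p = 2.78e-19) and RTS0112947 by -6.96 ± 0.39 (adjusted p = 3.02e-15), both in 24 of 24 tumours. RTS0112269 was higher by 9.01 ± 2.73 (adjusted p = 0.049) and RTS0113569 by 7.50 ± 2.24 (adjusted p = 0.0461), again in 24 of 24 tumours. RTS0112269 ranged from 11480 to 575200 CPM over the tumours and was at 242.4 CPM in liver. Both of these calls lay close to the threshold. That of RTS0112269 ended, with adjusted p up to 0.0588, without any 1 of the tumours 309, 501, 502, 701, 702, 809, 1001, 1701, 1801, 2201, 2203, 2204 and 2206, and without liver replicate 1 or 4. That of RTS0113569 ended, with adjusted p up to 0.0556, without any 1 of 701, 702, 1001, 1701, 2201, 2203 and 2206. On array 1 alone adjusted p was 0.0596 for RTS0112269 and 0.0575 for RTS0113569.

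The balance of higher and lower probes depended on the test. DESeq2 called 72 higher and 95 lower against kidney, 32 and 49 against spleen, and 132 and 110 against liver. limma with voom on regions called 133 and 106, 78 and 46, and 261 and 90, so the number lower differed less between the 3 tests than the number higher.

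The number higher also moved with the scaling, the regions used and single tumours. Upper quartile scaling gave 15 higher against kidney, and 30 higher and 332 lower against liver. Library size alone gave 4 higher and 122 lower against spleen and 5 higher against liver. Array 2 alone gave 8 higher against kidney and 1 against spleen, and array 1 alone gave 4 against liver. Without spleen replicate 2 there were 2 higher against spleen. Without the 17 tumour regions of lowest total, left out after seeing the data, there were 8 higher against kidney and 1 against spleen. Leaving out 1 tumour, also chosen after seeing the data, gave 4 to 11 higher and 94 to 101 lower against kidney, with 11 without tumour 1403 and 10 without 214 or 404. It gave 0 to 2 higher and 41 to 55 lower against spleen, with 2 without tumour 214 or 404. It gave 6 to 18 higher and 85 to 109 lower against liver, with 6 without tumour 1001, 2201 or 701 and 18 without 214.

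Probe sets chosen as higher in 1 control tissue than in the other 2 were used to describe the tumours. A sample unrelated to all 3 is expected to lie between the tissues used for the choice, so these levels alone do not show resemblance. The spleen-high set, 99 probes chosen from the control regions alone, was at 8.58 ± 0.29 log2 CPM in the tumours (SD, n = 24). It was at 9.47 ± 0.08 in spleen, 7.35 ± 0.02 in kidney and 7.68 ± 0.07 in liver (SD, n = 4 regions each). The 4 regions may hold repeats of a place across the arrays. In kidney, replicates 1 and 3 and replicates 2 and 4 had a chi-square per degree of freedom of 1.32 and 1.42, against 3.18 and 3.08 within arrays. In liver these were 1.92 and 1.29 against 2.98 and 2.61, and in spleen 1.27 and 1.16 against 1.74 and 1.26. These SDs may therefore understate the spread. All 24 tumours were above every kidney and liver region and below every spleen region. With upper quartile scaling 17 of 24 were above every kidney and liver region, and with library size alone 12 were, with all 24 below spleen in both. Tumour 706 was highest at 9.21 and tumour 214 lowest at 8.01, a 2.29-fold range. Of the 99 probes, 65 had a tumour mean above both other tissues and 20 had one above spleen itself, while 24 were called lower in the tumours than in spleen and 0 were called higher. The choice of these probes as high in spleen favours calls lower in the tumours, and the same holds for the other sets.

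The kidney-high set of 131 probes was at 8.27 ± 0.27 log2 CPM in the tumours, against 9.90 ± 0.07 in kidney, 7.72 ± 0.03 in spleen and 7.90 ± 0.14 in liver. In 19 of 24 tumours the level was above every spleen and liver region, but in 0 with upper quartile scaling and in 0 with library size alone. The SD over tumours depended on the scaling too. With upper quartile scaling and sets chosen again it was 0.149 for kidney-high and 0.344 for liver-high, against 0.273 and 0.203 with TMM. Tumour 309 was highest at 8.71 and tumour 214 lowest at 7.84. Of its probes, 53 were called lower in the tumours than in kidney. The liver-high set of 46 probes stood differently. At 7.15 ± 0.20 in the tumours it lay near its level in spleen (7.07 ± 0.05) and kidney (7.43 ± 0.05) and far below liver (10.01 ± 0.28), 36 of its probes were called lower than in liver, and 1 of 24 tumours exceeded every kidney and spleen region.

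As a reference for an unrelated sample, probes were also chosen from 2 control tissues and the third was placed between them, with 0% for the low and 100% for the high tissue. The scalings of set levels and this reference were chosen after seeing the data. For probes higher in spleen than in kidney, liver lay at 26.3% and the tumours at 54.6% ± 13.6 (SD, n = 24). For probes higher in spleen than in liver, kidney lay at 24.3% and the tumours at 72.1% ± 17.7. With upper quartile scaling the first pair was 40.7% and 34.5% and the second 10.4% and 40.5%. With library size alone they were 25.7% and 6.4%, and 19.6% and 15.1%. For probes higher in spleen, where the tumours lay relative to an unrelated tissue therefore depended on the scaling, and so it did for probes higher in kidney. For probes higher in liver than in kidney, the tumours lay below spleen under each scaling (13.4% against 37.2% with TMM). For probes higher in liver than in spleen, they lay below kidney under each scaling (7.3% against 50.4% with TMM).

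**Figure D2:**
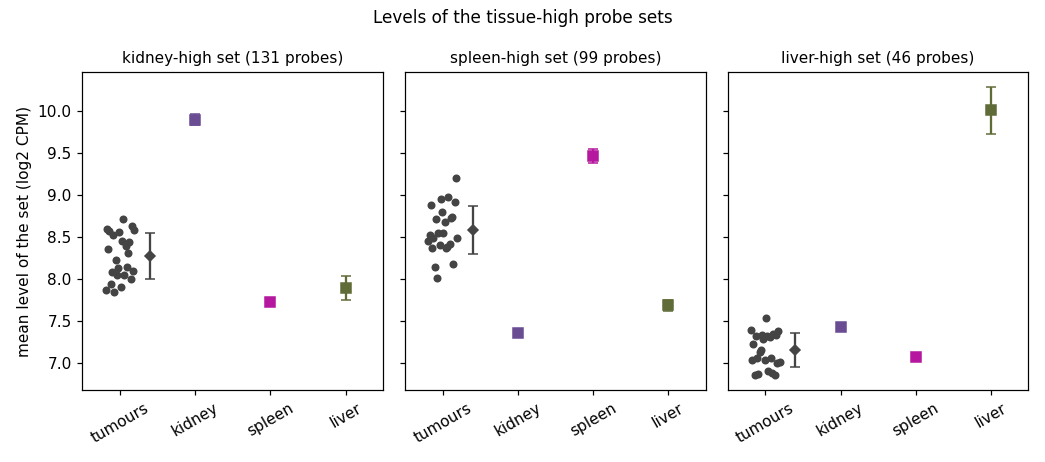
Mean level in log2 CPM of the kidney-high, spleen-high and liver-high probe sets. Grey points are the 24 tumours, the diamond is their mean with SD, and coloured squares are the means of 4 control regions with SD. With TMM scaling, tumours lie between spleen and the other tissues for the spleen-high set (mean 8.58) and near the low tissues for the liver-high set (mean 7.15).

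With TMM scaling, the levels of these sets were related to each other and to depth across the 24 tumours, but none of the 3 relations past the threshold held under the other scalings. Tumours with more kidney-high signal had less liver-high signal (Pearson r = -0.683, permutation p = 0.00045, adjusted 0.0045, Spearman rho = -0.701, permutation p = 0.00025, adjusted 0.00205). Without the 2 farthest tumours r was -0.707, and within arrays 1 and 2 it was -0.652 and -0.512. It was -0.491 with upper quartile scaling (adjusted 0.0606) and of opposite sign, 0.707, with library size alone. With library size alone, each set level fell as the share of the 10 highest probes rose (r = -0.973 for kidney-high, -0.927 for spleen-high and -0.732 for liver-high). The kidney-high level also increased with the log2 total count (r = 0.638, permutation p = 0.00093, adjusted 0.00465, rho = 0.671, permutation p = 0.00041, adjusted 0.00205), with r = 0.707 without the 2 farthest tumours and 0.607 and 0.636 within arrays, but 0.457 with upper quartile scaling (adjusted 0.0606) and -0.208 with library size alone. The spleen-high level also increased with it (r = 0.501, permutation p = 0.0125, adjusted 0.0417, rho = 0.497, permutation p = 0.014, adjusted 0.0467), with r = 0.428 without the 2 farthest tumours and 0.369 and 0.548 within arrays, but 0.104 with upper quartile scaling and -0.214 with library size alone. With TMM, the other 7 of the 10 relations did not pass the adjusted threshold, among them spleen-high against kidney-high (r = 0.341, permutation p = 0.104, adjusted 0.173, rho = 0.300, permutation p = 0.156). The latter was -0.443 with upper quartile scaling (adjusted 0.0606) and 0.856 with library size alone (adjusted 2.5e-05). With library size alone, spleen-high against liver-high (r = 0.849), liver-high against depth (r = -0.563) and each set against the share of the 10 highest probes passed as well.

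The tumours differed widely from each other. By the edgeR F test, 1738 of 2010 probes differed among the 24 tumours by more than the spread within tumours. In 14 tumours that spread is only the one between 2 arrays. It is small, with a biological coefficient of variation of 6.73% between the summed arrays of a tumour against 26.6% and 27.7% between 2 regions on an array. The 1738 probes therefore do not set tumours against separate regions of a tumour alone, and neither does the share of variance below. Among the 10 tumours with 2 regions on an array, 728 probes differed on array 1 and 631 on array 2, with median shares of 39.2% and 28.8%, an alternative with fewer regions that was chosen after seeing the data. Over all regions the tumour accounted for a median of 35.9% of a probe's variance over regions, with quartiles of 16.2% and 63.3%. The median was 62.5% among probes above the median level and 18.4% among the rest. With all regions thinned to 17711 counts it fell to 19.8%, so the share depends on depth. It was 43.6% with upper quartile scaling and 65.7% with library size alone, so it depends on the scaling as well. It exceeded 90% for 34 probes. The tumour accounted for 81.3% of the variance of the kidney-high level, 74.2% of the spleen-high level and 59.1% of the liver-high level.

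The probe with the largest share was RTS0112944 at 96.8% (edgeR adjusted p = 4.004e-29). Its level was 10.50 ± 0.99 log2 CPM (SD, n = 24 tumours) and ran from 8.99 in tumour 901 to 13.06 in tumour 404, a 16.8-fold range. The next was RTS0112273 at 96.6% (adjusted p = 6.407e-28), which ran from 6.71 in tumour 1002 to 16.85 in tumour 901, a 1125-fold range, with a mean SD of 0.29 between regions of a tumour. The 503 lowest probes had a mean of 6.21 in tumour 1002, so the low end of this range may hold background.

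Regions of 1 tumour resembled each other across the arrays. For 64 of 68 regions, or 94.1%, the most similar region on the other array came from the same tumour, where reassigned tumour numbers gave a mean of 3.18 regions (one-sided permutation p = 1e-05, the smallest the permutations can give). Centred profiles correlated with a median r of 0.623 for the 54 pairs of regions of a tumour on different arrays and 0.384 for the 20 pairs on the same array. For pairs from different tumours the medians were -0.034 and -0.050. These correlations are across probes, which are not independent replicates. The biological coefficient of variation between tumours was 41.5%.

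**Figure D3:**
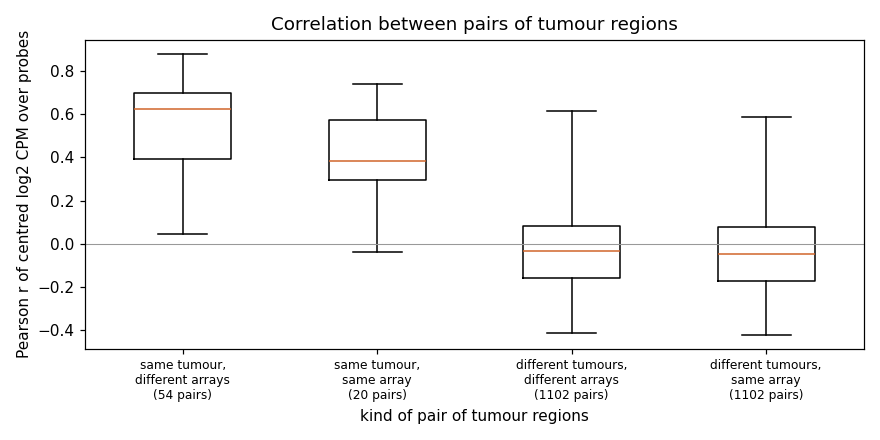
Pearson r of centred log2 CPM over probes for pairs of tumour regions, by whether they came from the same tumour and the same array. Boxes span the quartiles, the line is the median and whiskers reach the lowest and highest pair. Median r was 0.623 for regions of a tumour on different arrays and 0.384 for regions of a tumour on the same array.

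The arrays hold the same tumours, so array 2 was compared with array 1 within tumours. Tumour regions on array 2 had lower total counts, with a mean log2 difference of -0.615 ± 1.101 (SD, n = 24 tumours) or 0.653 of the total on array 1 (two-sided permutation p = 0.0115, lower in 14 of 24 tumours). By the edgeR test with the tumour as a block, 154 probes were higher and 22 lower on array 2, of 2008 tested, and the named differences were small. RTS0113657 was higher by a log2 fold change of 0.33 ± 0.06 (SE, adjusted p = 0.000174, higher in 20 of 24 tumours) and RTS0112344 by 0.31 ± 0.06 (adjusted p = 0.000934, higher in 19 of 24 tumours). RTS0112785 was lower by -0.44 ± 0.12 (adjusted p = 0.0155, higher in 3 of 24 tumours) and RTS0113850 by -0.46 ± 0.13 (adjusted p = 0.0241, higher in 9 of 24 tumours). The call of RTS0113850 ended without tumour 701 (adjusted p = 0.0777) or 1002 (adjusted p = 0.151), and that of RTS0112785 without tumour 1001 (adjusted p = 0.06). Without the tumour block none of these 4 probes passed, with adjusted p from 0.96 to 0.997. In the 10 tumours with 2 regions per array the log2 fold change was 0.17 for RTS0113657 (adjusted p = 0.278), -0.55 for RTS0113850 (adjusted p = 0.118) and -0.43 for RTS0112785 (adjusted p = 0.13). Only that of RTS0113657 shrank much, and the other calls ended with fewer tumours at much the same size. With the first region of each tumour it was 0.30 for RTS0112344 (adjusted p = 0.0531) and -0.49 for RTS0112785 (adjusted p = 0.066). In the other 14 tumours it was 0.33 (adjusted p = 0.176) and -0.48 (adjusted p = 0.316).

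The direction of the array difference depended on scaling. Upper quartile scaling gave 37 higher and 54 lower, and library size alone 19 higher and 76 lower. The number lower was 13 with DESeq2, 4 with the first region of each tumour and 2 in the 10 tumours with 2 regions per array. Leaving out 1 tumour, chosen after seeing the data, gave 103 to 176 higher and 12 to 23 lower, with 12 lower without tumour 1001 and 13 without 610 or 1002. An array effect was called for 0 probes in the control tissues and for 150 in the tumours of the same edgeR fit. The former rests on 3 tissues and the latter on 24 tumours, so these numbers do not show that the effects differ. The test of the difference between them called 0 probes. Of 2010 probes, 55 were at an unadjusted p under 0.05, no larger a share than chance alone gives.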

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

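The no-template control, a library made without tissue, was not part of any comparison and is given here because it held counts above the 3 that a count of 0 allows. Its total count was 74 over 38 probes, 34 of them with a count of 1, which equals 0.418% of the lowest total of a tissue region. The highest count of a probe was 17. It was shared by RTS0112268 and RTS0112269, named here after their values were seen, which together held 45.9% of the control's counts. The control had 691787 raw reads, of which 385 aligned. Among the 3 control tissues, 27 tests of whether 1 of 4 regions lay far from the others, on depth, probe shares and set levels, marked no region.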

How the results depend on the processing

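Named probes kept their direction under every alternative that gave them an adjusted p, 2 array probes having none under DESeq2. Total counts of changed probes not given here stayed within 1.5 times the value reported. The cause of the following shifts was not tested, except that fewer samples or shallower counts enter by construction where named. Against kidney, spleen and liver, DESeq2 called 167, 81 and 242 probes, limma with voom 239, 124 and 351, and regions as samples, whose p-values are too small because regions share tumours, 687, 682 and 1138. Upper quartile scaling called 362 against liver, and library size alone called 126 against spleen. These scalings moved the median log2 fold change of all probes from 0.01, 0.02 and 0.03 against kidney, spleen and liver to -0.34, -0.31 and -0.63 and to -0.77, -0.997 and -0.79, so directions are relative to the scaling. The array count was 91 with upper quartile scaling, 95 with library size alone, 1 with no tumour block, 29 with the first region of each tumour, 51 in the 10 tumours with 2 regions per array and 1 in the other 14 tumours, with 236 at an unadjusted p under 0.05. Differences among tumours fell to 728 and 631 probes in the 10 tumours on array 1 or 2 alone. The median share of variance between tumours was 43.6% with upper quartile scaling, 65.7% with library size alone, 19.8% with regions thinned to the lowest total and 28.8% in 10 tumours on array 2 alone. The SD of set levels over tumours, 0.273 for kidney-high, 0.289 for spleen-high and 0.203 for liver-high, was 0.326, 0.354 and 0.224 with a 2 log2 rule. With upper quartile scaling it was 0.149 for kidney-high and 0.344 for liver-high, and with the median over the set 0.386 for spleen-high and 0.249 for liver-high. Leaving out 1 control region gave 100 to 111, 41 to 50 and 99 to 106 probes. The following were chosen after seeing the data. Leaving out 1 tumour gave 98 to 110 probes against kidney, 41 to 55 against spleen, 91 to 125 against liver and 123 to 199 between arrays. Without the 17 tumour regions of lowest total these counts were 104, 52, 128 and 158. With upper quartile scaling and with library size alone, r of kidney-high with liver-high was -0.491 and 0.707, of kidney-high with depth 0.457 and -0.208 and of spleen-high with depth 0.104 and -0.214. The sign of each changed with library size alone, but for the relations with depth the permutation p was then 0.328 and 0.313. Tumours above both other tissues were 0 and 0 for kidney-high, 17 and 12 for spleen-high and 1 and 0 for liver-high. The single-array values among tumours belong here too. Depth limits low probes most, since the median count per probe was 2 in the shallowest tumour region. The preset gene lists were not run.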

Other observations

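Some probes were high in a single tumour. With the requirement that every region of a tumour lie at least 2 log2 units above the mean of each other tumour, 7 probes met it, in 6 of the 24 tumours. RTS0112954 was at 10.26 log2 CPM in tumour 601, 17.9-fold above the median of the other tumours, with counts of 115 and 124 in its 2 regions and a highest control region at 7.50. RTS0111919 was at 13.67 in tumour 309, 13.0-fold above the median of the others, with counts of 1363 and 1572. The rule and both names were chosen after the values were seen, and no test was made.

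Regions of a tumour also differed in how much of their counts the 10 highest probes held, and the difference recurred on the other array. In the 10 tumours with 2 regions per array it reached 23.4 percentage points in tumour 404 on array 1 and 22.5 on array 2, with medians of 5.99 and 4.80 over the tumours. The differences on the arrays correlated (Pearson r = 0.982, permutation p = 3e-05, Spearman rho = 0.915, permutation p = 0.00065, r = 0.950 without the 2 farthest tumours).

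Of the tests below, the correlation of matched regions and the main axis with every region thinned to the same total were set before their results were seen, and all others after. A candidate explanation for regions pairing across arrays is that the same place in the tumour lay on both arrays. Regions were matched on alternate probes and the match was judged on the rest. In 5 of the 10 tumours both matched regions correlated better across arrays than the 2 regions of the same array did. This is at the bound first written as counting against the explanation, so by that bound the correlation with all counts went against it. The median r was nevertheless 0.67 for matched regions and 0.368 for regions of the same array. With every region thinned to 17711 counts the number of such tumours was 9 of 10, so like depth is argued against as the source of the match. In differences of counts, the chi-square per degree of freedom of both matched pairs was below that of both same-array pairs in 10 of 10 tumours with all counts and in 9 of 10 with the 4 regions of a tumour thinned to equal totals, tumour 610 being the exception. The differences of counts fit the same place lying on both arrays, while the correlation with all counts was at the bound written against it. The rule for the verdict was changed to rest on equal totals after the values were seen, so no verdict is drawn. The same place on both arrays stays a hypothesis, and no biological explanation was tested.

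The differences between the arrays in the tumours are small, and several sources were weighed. Chance is argued against as the source of the number of calls, 176. Exchanging array labels within tumours in 60 splits, the real one included, gave as many only in 1, the real one, and the highest other gave 1. A share of 1 of 60 is the smallest these splits can give. It concerns the number of calls and does not vouch for each probe. A lower depth of array 2 is argued against as the whole source, because 126 probes were called with the arrays of each tumour thinned to 1 total. The larger number of higher than lower probes may come from the choice of scaling, since 40.7% of calls were higher with upper quartile scaling against 87.5% with TMM. The array is a technical unit and no biological explanation was tested.

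The main axis of variation among the tumours, the first principal component of the 1507 probes of higher level, held 23.0% of their variance. It correlated with the mean level of the 503 lowest probes, which were left out of it (Pearson r = 0.865, permutation p = 1e-05, the smallest possible, Spearman rho = 0.843, permutation p = 1e-05, r = 0.825 without the 2 farthest tumours). A share of non-specific background in each tumour would give such a relation. With library size alone the main axis was another, yet its r with the lowest probes was 0.834. The relation thus arose for unlike axes and cannot single out background, which stays a hypothesis. The axis with TMM also ran with the kidney-high level (r = -0.965) and the liver-high level (r = 0.764). Probes of these sets were left out of the axis only if among the 503 lowest, so these values are not independent of it. Whether the relation between those sets with TMM comes from background was not tested. Counting depth is argued against as the whole source, since the axis from thinned counts ordered the tumours alike (r = 0.860), although the log2 total count itself correlated with the axis (r = -0.651). A few probes taking most of the counts is argued against by r = 0.113 with the share of the 10 highest probes, 95% interval -0.305 to 0.494, but only for the axis with TMM, since with library size alone, which leaves that share in, the axis was another (r = 0.163 with the former) and ran with it (r = -0.949). A difference between tumours in cell content stays open, and no biological explanation was tested.

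Other groupings of the samples were tried in the remaining comparisons. Taking each tumour in turn as the lone sample gave 25 splits per tissue, the real one included. Only the real one, 1 of 25, reached 103 probes for kidney and 101 for liver, with 35 and 38 as the highest others. A share of 1 of 25 is the smallest these splits can give. Each tissue is 1 summed sample, and the other splits place it among the tumours. The lone tissue thus stood out more than any lone tumour, but chance is not taken as excluded. For spleen the real 48 stood against 40, and on array 1 alone 39 against 31, again 1 of 25 each. With DESeq2 size factors 2 of 25 reached the real 38, the other giving 41. Whether the real split stood out for spleen therefore depended on the scaling, and chance is not taken as excluded there either. Each of these highest others had tumour 404 as the lone sample. For differences among tumours, 1 of 30 splits, the real one, reached 1738 probes, and the highest other reached 111. These splits part regions that pair across the arrays, which raises the spread within a tumour number. They show that tumour numbers go with the profiles. They cannot show that tumours differ by more than separate places in a tumour do.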
